A study of Homo sapiens with 8 samples.

How the data were processed

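Gene expression was measured on 8 arrays from BT-474, an established human breast cancer cell line with amplified HER2, the receptor to which the antibody trastuzumab binds. Per the labels, the arrays fell into 4 groups of 2: sensitive cells without antibody, sensitive cells with trastuzumab, resistant cells without antibody, and resistant cells with trastuzumab. Per the labels' protocols, the resistant population had been grown in 15 µg/ml trastuzumab for at least 8 months, total RNA was extracted with a column kit, and it was labelled with biotin for whole-transcript arrays. The dose and length of the treatment of the sensitive cells, and the time that untreated resistant cells spent without antibody, are not given in the sources used here. The protocol text speaks of resistant populations of 4 cell lines, while every sample title names BT-474. Whether the treated and untreated arrays of a population came from 1 line is therefore read from the titles alone, and a difference called a response to trastuzumab rests on that reading. The series design speaks of triplicates, while 2 arrays per group were analysed here. No label says whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

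The authors' deposited table holds log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA, which corrects background, sets the arrays to 1 common distribution and summarises the probes of a probe set, and the oligo package, with no version. The 8 arrays had medians of 5.10 to 5.18 and standard deviations over probe sets of 2.14 to 2.18, as close as values scaled to each other would be, and no further scaling was applied. Because RMA pulls the arrays to a common distribution, a change of total RNA per cell would not be seen. For arrays the number of arrays, not a read depth, limits the precision: 4 residual degrees of freedom were left over 8 arrays, and the moderation of the variance added 4.77.

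The table lists 53981 probe sets, of which 364 held no values. The platform annotation used here pairs 16098 of the others with 1 gene symbol, 0 with several, and leaves 37519 unnamed here. All 16098 gene identifiers were matched in the RefSeq gene table of assembly GRCh38.p14, which gave current symbols and the order of genes along chromosomes. The array's genome build is not stated, so no coordinates are given. Of several probe sets of a gene (779 genes) the one with the highest mean over the 8 arrays was used, which left 14884 genes, among them 11916 protein-coding genes, 1398 long noncoding RNAs and 1072 microRNA genes. No filter on dim probe sets was applied. The gene of HER2 itself, mucins, replication-dependent histones and mitochondrially encoded genes carry no name in the annotation used and were not analysed here.

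Genes were tested with limma 3.58.1 in R 4.3.3: a linear model with 1 mean per group, 6 comparisons, moderated statistics without a trend, two-sided, and Benjamini-Hochberg adjustment over the 14884 genes with a threshold of 0.05. The comparisons were resistant against sensitive cells without antibody, the same with antibody, treated against untreated sensitive cells, treated against untreated resistant cells, the mean of the first pair, and the interaction, which is the response of resistant cells minus that of sensitive cells. Fold changes are differences of mean log2 values. The replicate number was not used to pair arrays.

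The genes named were chosen by a rule: for each comparison the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap (5 each way for the averaged comparison and the interaction), leaving out open reading frames, antisense and uncharacterised transcripts and small RNA classes. Up to 4 members of each gene list were added, those that passed first, and 4 fixed genes (ERBB3, EGFR, ESR1 and CCNE1). Where another gene is named, that is said. Before the data were examined, 38 gene lists had been fixed for signalling, cell cycle, lineage, immune, metabolic and stress genes and for markers of other cell types; 33 had at least 5 measured members and were tested with camera at its preset correlation of 0.01, adjusted over the 33 lists, with an estimated correlation and with fry as alternatives. Some lists were measured only in part, such as 9 of 23 basal, 20 of 38 ribosomal, 8 of 18 blood and immune and 6 of 14 fibroblast genes. Members that passed are counted over all genes and adjusted over the list alone. The list score of an array is the mean of its members' deviations from their means over the 8 arrays.

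The model was tested on simulated values for 14884 genes with the spread of the real arrays. For the comparison of untreated cells it recovered 25.7% of genes changed by 0.5 on the log2 scale, 76.7% of those changed by 1 and 100% of those changed by 2. For the response of resistant cells these shares were 38.5%, 76.2% and 100%, and for the interaction 4.84%, 63.6% and 94%. At 0.5 they rest on 18 of 70, 30 of 78 and 3 of 62 genes, so 25.7% and 38.5% do not show different power. The simulation for untreated cells gave 142 calls against 1100 in the data. With more changed genes the adjusted threshold is less strict, so these shares are only a rough guide. Alternatives fixed before the data were examined were centring or quantile normalization of the arrays, a filter on dim genes, a variance trend with robust moderation, array weights, only the 4 arrays compared, a replicate block, the mean of a gene's probe sets, all probe sets, a minimum change of 1 on the log2 scale, and leaving out each array in turn. Leaving out arrays for list tests and for correlations between comparisons, and the whole study of neighbouring genes, were added after seeing the data. Plots were drawn with matplotlib 3.10.9.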

Results

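Transcript levels were compared between trastuzumab-sensitive and trastuzumab-resistant BT-474 cells, each with and without trastuzumab, on 2 arrays per group. The series addresses mechanisms by which these HER2-positive cells become resistant to the antibody. Arrays of a group correlated at r = 0.9937 to 0.9955 over the 14884 genes, arrays of the same cells with the other treatment at 0.9886 to 0.9942, and arrays of different cells at 0.9784 to 0.9874. These are correlations across genes, which are not independent replicates. The median standard deviation between the 2 arrays of a group was 0.0703 to 0.0946. A principal component analysis placed the cell populations apart on the component with the most variance (50.1%) and the treatments apart on the next (16.3%).

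**Figure D1:**
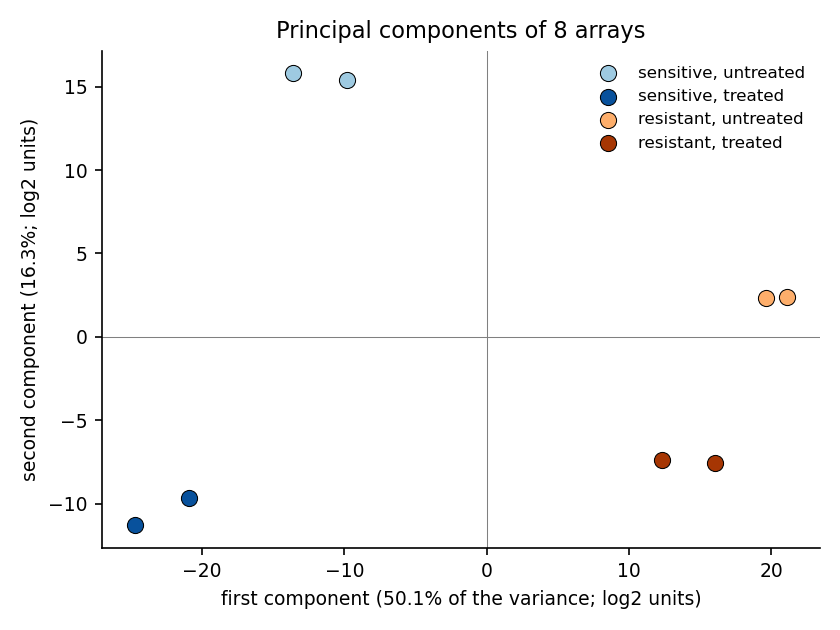
Principal components of the 14884 genes, 1 point per array, with the share of variance on each axis in percent. Sensitive arrays lie at -24.7 to -9.8 and resistant arrays at 12.3 to 21.1 on the horizontal axis, and untreated arrays lie above treated arrays of the same cells on the vertical axis.

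Without antibody at harvest, resistant cells expressed far more of the chemokines CCL5, CXCL10 and CXCL11 and of many interferon-stimulated genes than sensitive cells, and far less of several secretory and epithelial genes. CCL5, a chemokine that attracts T cells, was 30.2-fold higher (log2 difference 4.92, SE 0.17, adjusted p = 4e-06), rising from 5.77 ± 0.08 to 10.68 ± 0.04 (SD, n = 2 arrays). CXCL10, a chemokine induced by interferons, was 22.7-fold higher (4.50, SE 0.25) and CXCL11, which binds the same receptor, was 4.71-fold higher. In untreated sensitive cells CXCL10 (3.88), CXCL11 (4.77), IFIT3 (3.69), IFIT1 (4.22) and IFI44 (3.98) lay below the array medians, as did PIP in untreated resistant cells (4.76). These levels are not shown to be above background, so the folds of these genes are not exact. CCL5 in untreated sensitive cells (5.83 and 5.71) lay somewhat above the array medians. No limit of detection was set, so its fold is not shown to be exact either. PIP, a secretory protein of apocrine and mammary epithelium, was 17.1-fold lower (-4.09, SE 0.16, adjusted p = 8.4e-06), and FMOD, an extracellular matrix proteoglycan, was 6.81-fold lower (-2.77, SE 0.09). By limma with Benjamini-Hochberg adjustment, 1100 of 14884 genes changed, 639 higher and 461 lower in resistant cells, of which 67 and 64 differed by at least 2-fold.

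Interferon-stimulated genes rose as a group: 16 of 32 measured members were higher and none was lower, 19 when adjusted over the list alone, with a median log2 difference of 0.57 (camera adjusted p = 3.5e-12, and adjusted p = 0.034 with an estimated correlation). The largest rises were in IFIT3 (3.52, SE 0.29, 11.5-fold), IFI44 (2.77, SE 0.11), HERC5 (2.66), IFIT2 (2.60), IFIT1 (2.51) and IFI44L (2.26), whose products restrict viral RNA or translation or attach the ubiquitin-like ISG15. HERC5 (4.43 and 4.66 on the 2 arrays) and IFI44L (3.99 and 4.31) also lay below the array medians in untreated sensitive cells. IFIT2 lay near them (5.18 and 4.69), so the differences of HERC5, IFI44L and IFIT2 are not exact either. The RNA sensors RIGI and IFIH1 rose by 0.87 and 1.21. Other members did not pass and were near or below 0, such as IRF7 (0.12), SAMD9 (-0.19) and IFI35 (-0.35). RIGI, IFIH1, IRF7, SAMD9 and IFI35 lie outside the rule for named genes and were chosen after their values were seen. IL18, an interleukin of epithelial cells, fell by 1.78. Its levels in untreated resistant cells (4.11 and 4.26) lay below the array medians, so that difference is not exact. The wider list of inflammatory cytokines and NF-kB targets was not called (median -0.01 over 22 members, 3 higher and 1 lower). Its score, a mean over members, was higher by 0.36 (95% interval 0.24 to 0.48). The list's risers were CCL5, CXCL10 and CX3CL1 (0.90). Only 7 of 29 listed antigen presentation genes were measured, so most of that list was not tested. Of these 7 genes 1 was lower, over all genes and adjusted over the list alone (median -0.23, adjusted p = 0.047, and adjusted p = 0.34 with an estimated correlation). That call was lost without any untreated array or either treated sensitive array (adjusted p up to 0.087). Blood and immune cell markers showed no member past the threshold (median -0.15 over 8), nor did fibroblast markers (median -0.06 over 6), and 1 of 9 endothelial markers, ESAM, was lower (median -0.12), a call lost without any untreated array (adjusted p up to 0.16).

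**Figure D2:**
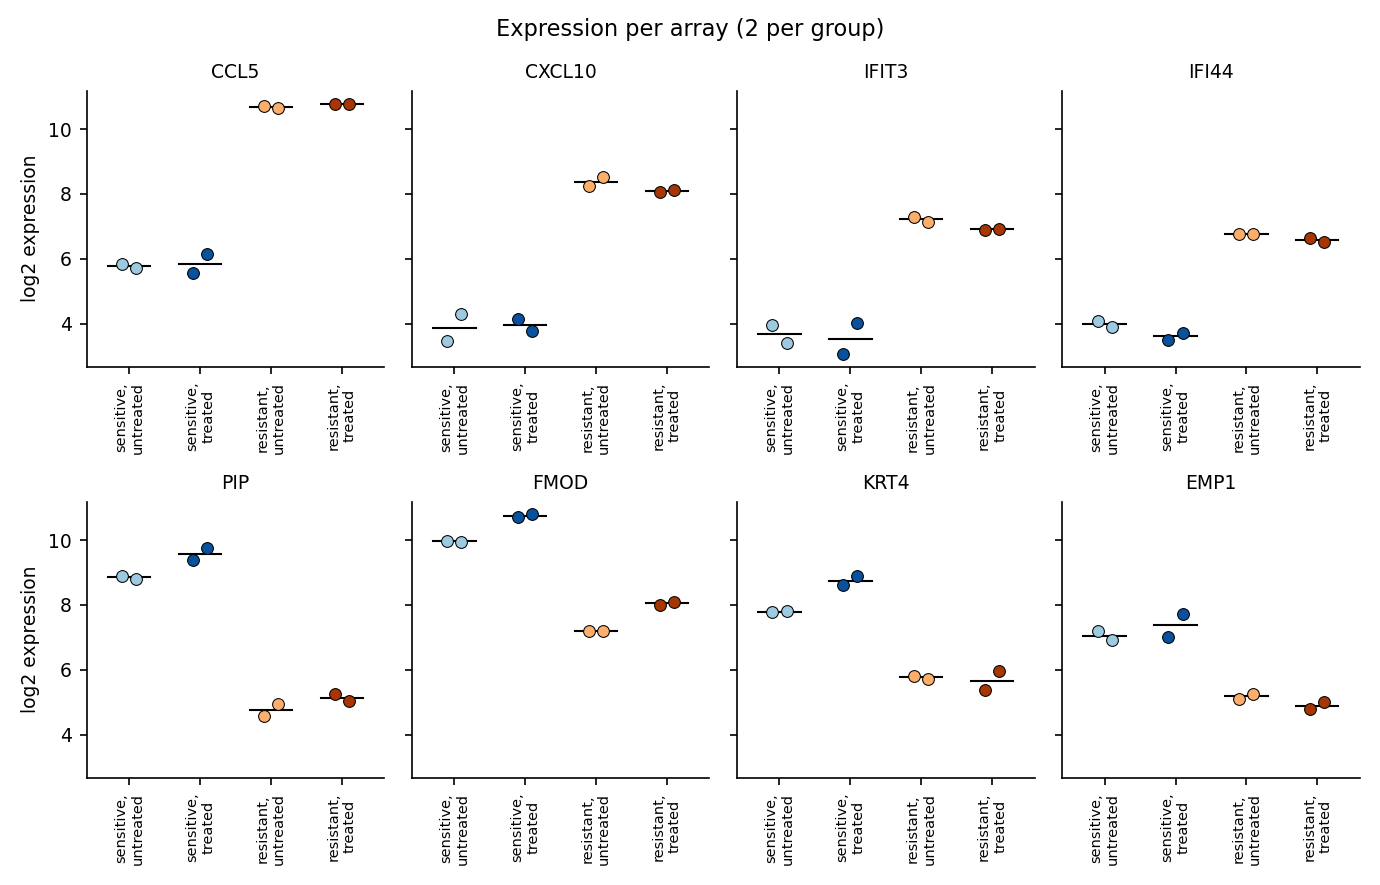
Log2 expression of 8 genes on each of the 8 arrays, with the points of a group around a line at its mean (n = 2). CCL5, CXCL10, IFIT3 and IFI44 lie higher on all 4 resistant arrays than on all 4 sensitive arrays, and PIP, FMOD, KRT4 and EMP1 lie lower; CCL5 averages 10.68 in untreated resistant and 5.77 in untreated sensitive cells.

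Lower genes of untreated resistant cells included UPK1A (-2.47), a urothelial membrane protein, the cystatin CST4 (-2.04), KRT4 (-2.03), a keratin of stratified epithelium, VSIG2 (-1.93), EMP1 (-1.87), PSCA (-1.85) and NIPAL3 (-2.00). CST4 has close paralogs whose transcripts its probes could share, and another probe set of NIPAL3 differed by 0.05. NIPAL3 lay below the array medians in untreated resistant cells (4.89 and 4.71) and EMP1 near them (5.09 and 5.26), so their differences are not exact. Fatty acid synthesis and lipid storage genes fell, with 8 of 22 lower and none higher (12 lower and 1 higher when adjusted over the list alone; median -0.31, adjusted p = 7.4e-05, and adjusted p = 0.13 with an estimated correlation). PPARG, a transcription factor of lipid storage, fell by 1.33, the desaturase FADS2 by 0.97, and the synthase FASN by 0.79. The levels of PPARG in untreated resistant cells (4.44 and 4.61) lay below the array medians, so its difference is not exact. Cholesterol synthesis genes had 4 of 17 lower, over all genes and adjusted over the list alone (median -0.17, adjusted p = 0.004, and adjusted p = 0.39 with an estimated correlation), among them DHCR7 (-0.69). Lysosome genes had 4 of 17 lower, 6 when adjusted over the list alone (median -0.25, adjusted p = 0.0016, and adjusted p = 0.33 with an estimated correlation), among them CTSD (-0.63).

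Only 9 of 18 listed mammary secretory and apocrine genes and 9 of 23 listed basal epithelial genes were measured. Much of both lists was therefore not tested. Mammary secretory and apocrine genes had 3 lower and 1 higher of 9, 4 lower and 1 higher when adjusted over the list alone (median -0.32, adjusted p = 0.012, and adjusted p = 0.29 with an estimated correlation). Besides PIP, CRISP3 fell by 1.25 and CLCA2 by 0.92, while DHRS2 rose by 0.68. CRISP3 lay near the array medians in untreated resistant cells (5.35 and 5.22), so its difference is not exact. Without array 2 of the untreated sensitive cells the secretory call was lost (adjusted p = 0.073). Basal epithelial genes had 3 of 9 lower, 5 lower and 1 higher when adjusted over the list alone (median -0.41, adjusted p = 0.036, and adjusted p = 0.38 with an estimated correlation), a call also lost without that array (adjusted p = 0.067). The calls of CTSD and CLCA2 were lost without array 2 and array 1 of the untreated resistant cells (adjusted p = 0.072 and 0.066), and that of DHRS2 without any untreated array (adjusted p up to 0.09).

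Some cell cycle and ribosomal genes were higher. Of 25 genes for the G1/S transition and DNA replication, 2 passed over all genes, EXO1 (0.51) and MCM4 (0.44), and 13 were higher and 1 lower when adjusted over the list alone (median 0.29, adjusted p = 7.4e-05, and adjusted p = 0.39 with an estimated correlation). Of 23 G2/M and mitosis genes, 2 passed over all genes and adjusted over the list alone, CCNB1 (0.57) and CDK1 (0.46), and the list was not called (median 0.10). The calls of EXO1, MCM4, CCNB1 and CDK1 had adjusted p of 0.21, 0.19, 0.21 and 0.23 without array 2 of the untreated resistant cells. They were lost too without array 1 of those cells or array 2 of the untreated sensitive cells, and without array 1 of the latter except for CCNB1. Cytosolic ribosomal protein genes had 3 of 20 higher, 8 when adjusted over the list alone (median 0.20, adjusted p = 1.2e-05, and adjusted p = 0.29 with an estimated correlation). EXO1, MCM4, CCNB1 and the ribosomal gene RPL35 lie in stretches of neighbouring genes that were higher together in resistant cells.

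Among other genes that rose were TEAD2 (2.11), a DNA-binding partner of the Hippo pathway, HEY2 (1.76), a Notch target, BCL2 (1.47), an inhibitor of apoptosis, and CXCL12 (1.08), a chemokine induced by oestrogen. The receptors FGFR4 (0.72), FGFR1 (0.70), MET (0.86) and ERBB4 (0.76) were higher, and FGFR1 lies in a stretch of genes that were higher together. Without array 2 of the untreated resistant cells the calls of MET and ERBB4 were lost (adjusted p = 0.067 and 0.068), as they were without array 2 of the untreated sensitive cells (0.063 and 0.052). Of 19 ERK output and feedback genes, 3 were lower and 1 higher, 6 and 1 when adjusted over the list alone. EMP1, DUSP6 (-1.21), a phosphatase induced by ERK, and SPRY2 (-0.47) fell and MYC rose by 0.61. SPRY2 lay near the array medians in untreated resistant cells (5.21 and 5.29), so its difference is not exact. The calls of SPRY2 and MYC were lost without array 1 of the untreated resistant cells (adjusted p = 0.18 and 0.076). Oestrogen receptor targets went both ways, with 7 higher and 2 lower of 20, 9 and 5 when adjusted over the list alone (median 0.04). ESR1, the oestrogen receptor, was 1.36-fold higher (adjusted p = 0.044), a call lost without any single resistant or untreated sensitive array (adjusted p up to 0.24). ERBB3, the partner of HER2, did not differ detectably (-0.02, SE 0.09, adjusted p = 0.93), nor did EGFR (0.31, SE 0.12, adjusted p = 0.16) or CCNE1, cyclin E1 (0.35, SE 0.12, adjusted p = 0.11). Of 13 measured genes beside that of HER2 in its amplicon, CDK12 was higher (0.44) and PNMT lower (-0.77), with a list median of 0.13. Both calls were lost without array 2 of the untreated resistant cells (adjusted p = 0.17 and 0.06). The count of 1100 was 526 and 350 without array 1 or 2 of the untreated sensitive cells and 317 and 265 without array 1 or 2 of the untreated resistant cells. The share of higher genes was 58.1% as deposited and 44.3% after quantile normalization (463 higher and 582 lower).

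With trastuzumab in both cultures, CCL5, CXCL10, interferon-stimulated genes and PIP again led the difference, and proliferation genes joined them. CCL5 was 30.3-fold higher in resistant cells (log2 difference 4.92, SE 0.17, adjusted p = 4.1e-06), CXCL10 17.5-fold higher (4.13), IFIT3 10.3-fold (3.36), IFIT1 8.63-fold (3.11) and IFI44 7.83-fold higher (2.97, SE 0.11). In treated sensitive cells CXCL10 (3.95), IFIT3 (3.54), IFIT1 (3.57) and IFI44 (3.61) again lay below the array medians, and their folds are not exact either. CCL5 (5.55 and 6.15) lay above the medians there, but without a limit of detection its fold is not shown to be exact. PIP was 21.6-fold lower (-4.44, SE 0.16, adjusted p = 4.2e-06), KRT4 8.51-fold (-3.09), FMOD 6.54-fold (-2.71) and DKK1, a secreted Wnt inhibitor, 5.78-fold lower (-2.53, SE 0.22). In treated resistant cells PIP (5.14) and DKK1 (5.20) lay close to the array medians, so their folds are not exact. ASS1, the arginine synthesis enzyme, was 5.76-fold higher (2.52, SE 0.13), and it lies at the end of a stretch of neighbouring genes that were higher together. In all, 1738 genes changed, 996 higher and 742 lower, 87 and 97 by at least 2-fold.

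Genes for the G1/S transition and DNA replication were higher in treated resistant than in treated sensitive cells: 23 of 25 over all genes and 25 when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 1e-21, and adjusted p = 0.17 with an estimated correlation). MCM10, a replication factor that helps activate the replicative helicase, was higher by 1.43 (SE 0.11), EXO1 by 1.18, cyclin E2 (CCNE2) by 1.08 and CLSPN by 1.05, although a dim probe set of CLSPN differed by 0.67. G2/M and mitosis genes had 16 of 23 higher, 22 when adjusted over the list alone (median 0.54, adjusted p = 2e-13, and adjusted p = 0.17 with an estimated correlation), with CCNB1 at 0.97, CDK1 at 0.89 and KIF11 at 0.71. Of the interferon-stimulated genes 16 of 32 were higher, 17 when adjusted over the list alone (median 0.49, adjusted p = 1.8e-08, and adjusted p = 0.076 with an estimated correlation).

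Oestrogen receptor targets had 10 higher and 2 lower of 20, 12 and 3 when adjusted over the list alone (median 0.46, adjusted p = 0.0033, and adjusted p = 0.41 with an estimated correlation). ESR1 itself was 1.87-fold higher (0.90, SE 0.11, adjusted p = 0.0016), BCL2, CXCL12 and MYB were higher by 1.06, 1.05 and 0.90, and AGR2, a disulfide isomerase of secretory cells, was lower (-0.91). CCNE1 was higher (0.66, adjusted p = 0.0091) and ERBB3 lower (-0.35, adjusted p = 0.043). CCNE1 lies in a stretch of genes that were higher together, and its call was lost without array 1 of the treated sensitive or of the treated resistant cells (adjusted p = 0.063 and 0.059). The ERBB3 call was lost without any 1 of the 8 arrays (adjusted p up to 0.19). Lysosome genes had 8 of 17 lower, 9 when adjusted over the list alone (median -0.39, adjusted p = 6.5e-06, and adjusted p = 0.17 with an estimated correlation), with HEXA, a lysosomal glycosidase, at -0.81. Of the 7 antigen presentation genes measured among 29 listed, 3 were lower, 4 when adjusted over the list alone (median -0.27, adjusted p = 0.027, and adjusted p = 0.21 with an estimated correlation). B2M, the light chain of class I molecules, was at -0.66 (0.05 on another probe set). The antigen presentation call was lost without array 1 of the treated resistant cells (adjusted p = 0.16) or array 2 of the treated sensitive cells (adjusted p = 0.051). Cholesterol synthesis genes had 4 of 17 higher, 7 higher and 1 lower when adjusted over the list alone (median 0.13, adjusted p = 0.044, and adjusted p = 0.46 with an estimated correlation). This call was lost without any 1 of the 4 treated arrays (adjusted p up to 0.09). Fatty acid synthesis genes (median -0.14), secretory genes (median -0.19), S100 and epidermal defence genes (median -0.10) and ribosomal genes (median 0.14) were called at adjusted p of 0.038 to 0.041 and at 0.21 to 0.41 with an estimated correlation; each was lost without array 2 of the treated resistant cells (adjusted p of 0.11, 0.1, 0.086 and 0.27) and without array 2 of the treated sensitive cells (0.089, 0.057, 0.057 and 0.089). Without array 1 of the treated resistant cells the fatty acid and S100 calls were lost (adjusted p = 0.055 and 0.057), and without array 1 of the treated sensitive cells the S100 call (0.069).

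HEY2 (2.32), FGFR4 (1.08), FGFR1 (0.80), TWIST1 (1.03), VIM (0.93) and ERBB4 (0.81) were again higher and SLPI (-1.36), PPARG (-1.33), SOX9 (-0.92) and BCL6 (-0.92) lower. PPARG lay below the array medians in treated resistant cells too (4.37 and 4.39), so its difference is not exact. TWIST1 lay near the medians in treated sensitive cells (4.91 and 5.3), so its difference is not exact either. TWIST1 and VIM belong to a mesenchymal transition list of 15 genes that was not called (median 0.06, 3 higher and none lower). That list's score, a mean over members, was higher by 0.19 (95% interval 0.07 to 0.31). The other probe sets of VIM differed by 0.23 and 0.01. The untreated and the treated comparison share no array. Their fold changes correlated at r = 0.691 (Spearman rho 0.538) across 14884 genes, which are not independent replicates, and 404 genes were higher and 309 lower in both against 42.8 and 23 for independent lists, with 2 in opposite directions. The calls of both used 1 variance per gene from all 8 arrays. The lists are therefore not independent, and the expected numbers are only a rough guide. Without array 1 of the treated sensitive cells 723 genes passed in the treated comparison, without array 2 1031, and without array 1 or 2 of the treated resistant cells 742 and 989.

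Over both treatment states the comparison of resistant with sensitive cells rested on 4 arrays against 4 and called 3001 genes, 1770 higher and 1231 lower, 66 and 74 of them by at least 2-fold. CCL5 (4.92, SE 0.12, adjusted p = 1.9e-07), CXCL10 (4.32), IFIT3 (3.44), IFI44 (2.87) and IFIT1 (2.81) led the rises and PIP (-4.26, SE 0.11, adjusted p = 2.9e-07), FMOD (-2.74), KRT4 (-2.56), UPK1A (-2.34) and EMP1 (-2.17) the falls. Of the interferon-stimulated genes 19 of 32 were higher and 1, IFI35 (-0.35, named after its value was seen), was lower, 21 and 4 when adjusted over the list alone (median 0.50, adjusted p = 5.2e-10, and adjusted p = 0.053 with an estimated correlation). Of the G1/S genes 21 of 25 were higher, 23 when adjusted over the list alone (median 0.52, adjusted p = 1.1e-14, and adjusted p = 0.19 with an estimated correlation). ESR1 (0.67, adjusted p = 6e-04) and CCNE1 (0.50, adjusted p = 0.0036) were higher, and ERBB3 (-0.18, adjusted p = 0.084) and EGFR (0.21, adjusted p = 0.12) did not pass. The count was 1864 without array 2 of the untreated resistant cells, and the share of higher genes was 59% as deposited and 49.8% after quantile normalization.

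**Figure D3:**
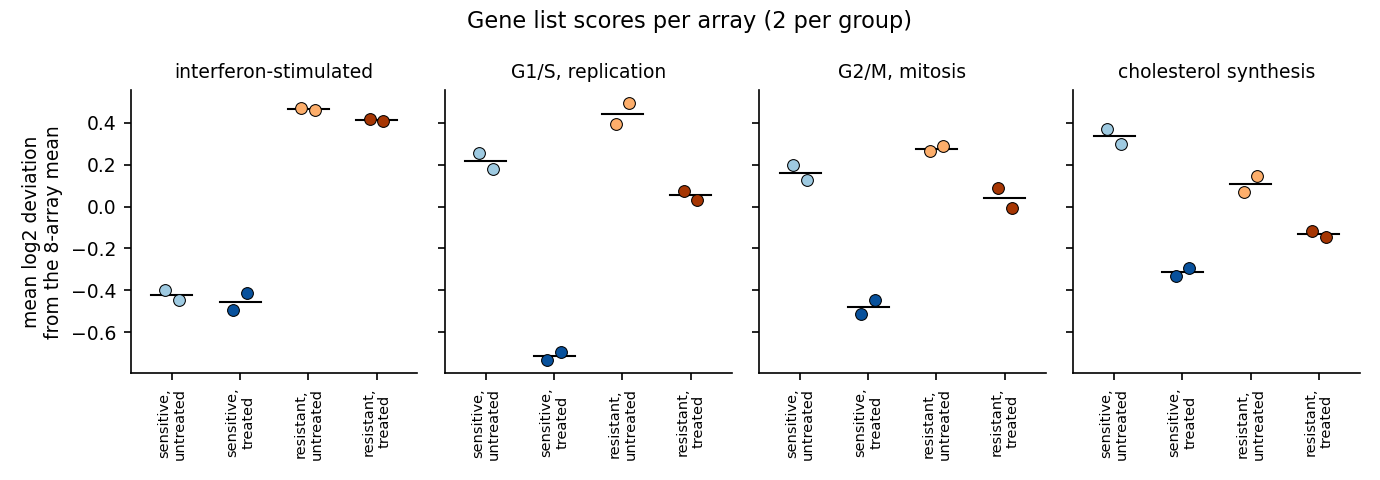
Scores of 4 gene lists on each of the 8 arrays (mean log2 deviation of the members from their means over the arrays), with a line at each group's mean (n = 2). Interferon-stimulated genes separate resistant from sensitive arrays with or without antibody (differences of 0.89 and 0.87), while the G1/S score falls with antibody by 0.93 in sensitive and by 0.39 in resistant cells.

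In sensitive cells, trastuzumab lowered the transcripts of DNA replication, mitosis and cholesterol synthesis and raised a smaller set that includes targets of FOXO transcription factors. MCM10 fell by 1.51 (SE 0.11, adjusted p = 0.001), the replication licensing factor CDC6 by 1.37, the cell cycle transcription factor MYBL2 by 1.30, the ubiquitin ligase adaptor DTL by 1.29 and CLSPN by 1.22. CALCOCO1, a receptor of selective autophagy, rose 3.06-fold (1.62, SE 0.09, adjusted p = 0.00062), PIK3IP1, an inhibitor of PI3K, 2.42-fold (1.28, SE 0.11) and SAT1, the polyamine acetyltransferase, 2.28-fold (1.19). By limma, 619 genes changed, 222 higher and 397 lower, 15 and 33 of them by at least 2-fold.

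All 25 measured G1/S and DNA replication genes were lower, over all genes and adjusted over the list alone, with a median of -0.91 and a range of -1.51 to -0.51 (camera adjusted p = 2.4e-35, and adjusted p = 0.049 with an estimated correlation). EXO1 fell by 1.13. Of the G2/M and mitosis genes 22 of 23 were lower, 23 when adjusted over the list alone (median -0.63, adjusted p = 4.2e-24, and adjusted p = 0.049 with an estimated correlation), with the mitotic kinesins KIF2C and KIF11 at -0.91 and -0.80 and CDK1 at -0.81. The kinase PBK fell by 1.14, the cohesion factor DSCC1 by 1.18 and the kinetochore protein SKA1 by 1.13. Without array 1 of the untreated sensitive cells the calls of KIF2C, KIF11, CDK1, DSCC1 and SKA1 were lost (adjusted p of 0.052 to 0.075), as they were without array 1 of the treated ones (0.054 to 0.077). Cyclin E1 fell by 0.78 (SE 0.12, adjusted p = 0.011), a call lost without either untreated array of these cells or array 1 of the treated ones (adjusted p up to 0.073).

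Cholesterol synthesis genes had 11 of 17 lower, 16 when adjusted over the list alone, and all 17 estimates were below 0 (median -0.69, adjusted p = 5.4e-17, and adjusted p = 0.049 with an estimated correlation). ACAT2, MVD and HMGCS1, enzymes of the early pathway, fell by 1.02, 1.02 and 1.00, and DHCR7, the enzyme of a last step, by 0.87. Fatty acid synthesis genes had 4 of 22 lower, 11 lower and 1 higher when adjusted over the list alone (median -0.31, adjusted p = 9.1e-07, and adjusted p = 0.049 with an estimated correlation), with the desaturase SCD at -0.87. FOXO targets had 6 of 19 higher, 7 when adjusted over the list alone (median 0.17, adjusted p = 3.3e-05, and adjusted p = 0.051 with an estimated correlation). PIK3IP1, KLHL24 (1.10) and YPEL3 (0.80) were among them, with ERBB3 (0.54, SE 0.09, adjusted p = 0.016). The calls of YPEL3 and ERBB3 were lost without any 1 of the 4 sensitive arrays (adjusted p up to 0.087 for each). ERK output and feedback genes had 4 of 19 lower, over all genes and adjusted over the list alone (median -0.17, adjusted p = 0.002, and adjusted p = 0.2 with an estimated correlation). EGR1 was at -1.07, with -0.25 on a dimmer probe set. DUSP6 was at -0.90 and DUSP4 at -0.64, calls lost without array 1 of the untreated sensitive cells (adjusted p = 0.054 and 0.066).

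Oestrogen receptor targets had 1 of 20 lower, MYBL1 (-1.02), and 10 lower and 1 higher when adjusted over the list alone (median -0.26, adjusted p = 0.00014, and adjusted p = 0.34 with an estimated correlation). The MYBL1 call was lost without array 1 of the untreated sensitive cells (adjusted p = 0.052), and ESR1 did not pass (-0.38, SE 0.11, adjusted p = 0.1). Lysosome and autophagy genes had 3 of 17 higher, 5 when adjusted over the list alone (median 0.07, adjusted p = 0.00064, and adjusted p = 0.2 with an estimated correlation), with GABARAPL1 at 0.68 and HEXA at 0.56, calls lost without array 1 of the untreated sensitive cells (adjusted p = 0.085 and 0.074). Amino acid and stress genes under ATF4 had 2 of 16 lower, 5 lower and 1 higher when adjusted over the list alone (median -0.12, adjusted p = 0.012, and adjusted p = 0.19 with an estimated correlation). The lower ones were the serine synthesis enzymes PSAT1 (-0.62) and PHGDH (-0.57), not called without array 1 of the treated sensitive cells (adjusted p = 0.074 and 0.071). The list's call was lost without array 2 of the treated sensitive cells (adjusted p = 0.1). Interferon-stimulated genes did not move as a group (median 0.05 and mean -0.03), and 1 of 32 passed, USP18 (-0.58), a call lost without either untreated sensitive array or array 1 of the treated ones (adjusted p up to 0.11). Other genes past the threshold were SFN (-0.90), ZNF83 (1.13), TCP11L2 (1.08) and CYBRD1 (1.02), an iron reductase. PIP rose by 0.72, a call lost without any sensitive or treated resistant array (adjusted p up to 0.18). EGFR did not pass (0.20, SE 0.12, adjusted p = 0.44). The count of 619 was 101 or 170 without array 1 or 2 of the untreated sensitive cells, 109 or 226 without array 1 or 2 of the treated ones, and 388 without either untreated resistant array, which enters only through the shared variance.

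In resistant cells no gene passed with trastuzumab, while G1/S, G2/M and cholesterol synthesis genes shifted down and FOXO targets up as lists. By limma 0 of 14884 genes changed (lowest adjusted p = 0.098), with 1373 at an unadjusted p under 0.05 against 744 expected by chance; the variance trend with robust moderation called 34 and the filter on dim genes 4. All 25 G1/S genes had estimates below 0, with a median of -0.39 against -0.91 in sensitive cells, and 22 were lower when adjusted over the list alone (camera adjusted p = 4.4e-23, and adjusted p = 0.13 with an estimated correlation). GINS2 was at -0.60 (SE 0.13, adjusted p = 0.34), CDC6 at -0.51 (SE 0.09, adjusted p = 0.31) and MCM10 at -0.50 (SE 0.11, adjusted p = 0.34). G2/M genes (median -0.22, adjusted p = 1.3e-10, and adjusted p = 0.13 with an estimated correlation) had 5 lower when adjusted over the list alone, and cholesterol synthesis genes (median -0.22, adjusted p = 1e-07, and adjusted p = 0.13 with an estimated correlation) 2, with DHCR7 at -0.44. FOXO targets had a median of 0.21 and 2 higher when adjusted over the list alone (adjusted p = 0.00099, and adjusted p = 0.13 with an estimated correlation), with KLHL24 at 0.60 (SE 0.09, adjusted p = 0.25) and YPEL3 at 0.51.

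Further called lists in resistant cells were ATF4 genes (median -0.18, adjusted p = 0.00095), fatty acid synthesis genes (-0.14, adjusted p = 0.0052), ERK output genes (-0.14, adjusted p = 0.0018), ribosomal genes (-0.10, adjusted p = 0.0019) and lysosome genes (0.08, adjusted p = 0.025), at adjusted p of 0.13, 0.13, 0.21, 0.31 and 0.41 with an estimated correlation. When adjusted over the list alone, 1 member passed in each of the ATF4 and ERK lists and 0 in the others. Without array 1 of the untreated resistant cells the ERK and lysosome calls were lost (adjusted p = 0.078 and 0.3), and without array 1 of the treated resistant cells the ribosomal and lysosome calls (adjusted p = 0.17 and 0.079). Without array 2 of the treated resistant cells the lysosome call was lost as well (adjusted p = 0.095). Interferon-stimulated genes had a median of -0.06. ERBB3 (0.21, SE 0.09, adjusted p = 0.54), ESR1 (0.08, SE 0.11, adjusted p = 0.87) and CCNE1 (-0.47, SE 0.12, adjusted p = 0.39) did not pass. Of the 619 genes called in sensitive cells, 568 had the same sign in resistant cells. Their medians were 0.58 for risers and -0.62 for fallers in sensitive cells, where they were selected and so are overstated, and 0.16 and -0.26 in resistant cells. The responses correlated at r = 0.326 (Spearman rho 0.285) across 14884 genes, which are not independent replicates.

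The interaction tested directly whether the responses differed. No single gene passed (0 by limma, lowest adjusted p = 0.28, with 1295 at an unadjusted p under 0.05 against 744 expected); the variance trend with robust moderation called 37. At 2 arrays per group the simulated interaction recovered 4.84% (3 of 62) of genes that differed by 0.5 on the log2 scale. The G1/S list was called: the median difference of responses was 0.53, that is, less lowering in resistant cells, and 20 of 25 members passed when adjusted over the list alone (camera adjusted p = 2.6e-22, and adjusted p = 0.14 with an estimated correlation). MCM10 differed by 1.00 (SE 0.15, adjusted p = 0.32) and CDC6 by 0.86 (SE 0.13, adjusted p = 0.32). G2/M genes differed by a median of 0.41 (6 of 23 when adjusted over the list alone; adjusted p = 2.6e-14, and adjusted p = 0.14 with an estimated correlation), with KIF11 at 0.67, and cholesterol synthesis genes by 0.39 (10 of 17; adjusted p = 1.5e-10, and adjusted p = 0.14 with an estimated correlation), with MVD at 0.75 and ACAT2 at 0.70. Fatty acid synthesis genes differed by a median of 0.22, with 1 of 22 when adjusted over the list alone (adjusted p = 0.0031, and adjusted p = 0.14 with an estimated correlation). ERBB3 (-0.33, SE 0.13, adjusted p = 0.52) and ESR1 (0.46, SE 0.15, adjusted p = 0.46) did not pass.

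**Figure D4:**
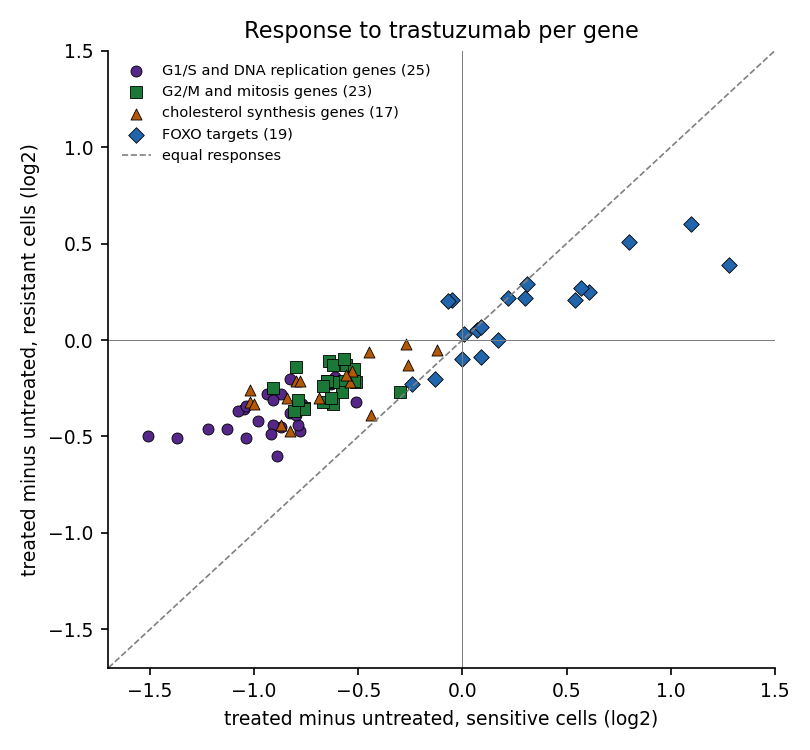
Response to trastuzumab of each member of 4 gene lists, with the log2 difference in sensitive cells on the horizontal and in resistant cells on the vertical axis and a dashed line where both are equal. The 25 G1/S and DNA replication genes lie between -1.51 and -0.51 in sensitive and between -0.60 and -0.19 in resistant cells.

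Genes that were higher in resistant cells lay next to each other more often than shuffled gene orders gave, an analysis chosen after seeing the data. With 9557 protein-coding genes (mean above 5) placed in chromosomal order, the running median of 21 neighbours of the resistant against sensitive difference over both treatment states reached 0.50. None of 1000 random shuffles of the gene order reached it (highest 0.41; permutation test over 9557 genes, p = 0.001, the smallest that 1000 shuffles can give). Windows past the shuffles' 95th percentile (0.311), joined where close, made 8 runs, all of higher expression, with 296 genes. The longest ran over 78 genes from MRPS30 to CCNH, with medians of 0.38 untreated and 0.35 treated and 47 genes called higher and 4 lower. Others were KCTD9 to SNAI2 (63 genes, 0.30 and 0.30), CNTRL to ZNF79 (30 genes, 0.38 and 0.34) and ODF2 to ASS1 (25 genes, 0.28 and 0.31); their end genes are named only as such. Genes named above that lie in the runs are ASS1, CCNB1, CCNE1, DSCC1, DUSP4, EXO1, FGFR1, MCM4, PBK and RPL35. Some runs were weak: HEATR1 to ZNF496 with EXO1 and KLF10 to DSCC1 each rested on 1 window (0.33). APAF1 to CKAP4 rested on 2 windows (at most 0.36) and ODF2 to ASS1 on 3 (at most 0.32). DSCC1 and ASS1 are end genes, which lie only in a run's outermost window. The difference of ASS1 given above is far larger than its run's medians. The run that holds CCNE1, TSSK6 to NUDT19 (36 genes), consists mostly of ZNF genes. Whether probes of that family share transcripts was not tested. For the responses to trastuzumab the largest window was 0.22 in sensitive cells, reached by 508 of 1000 shuffles, and 0.19 in resistant cells, reached by 61. Adjacent genes were nevertheless correlated beyond all 1000 shuffles in the responses too, at r = 0.04 in sensitive (highest shuffle 0.032) and 0.035 in resistant cells (0.03), against 0.151 for resistant against sensitive cells (0.031).

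**Figure D5:**
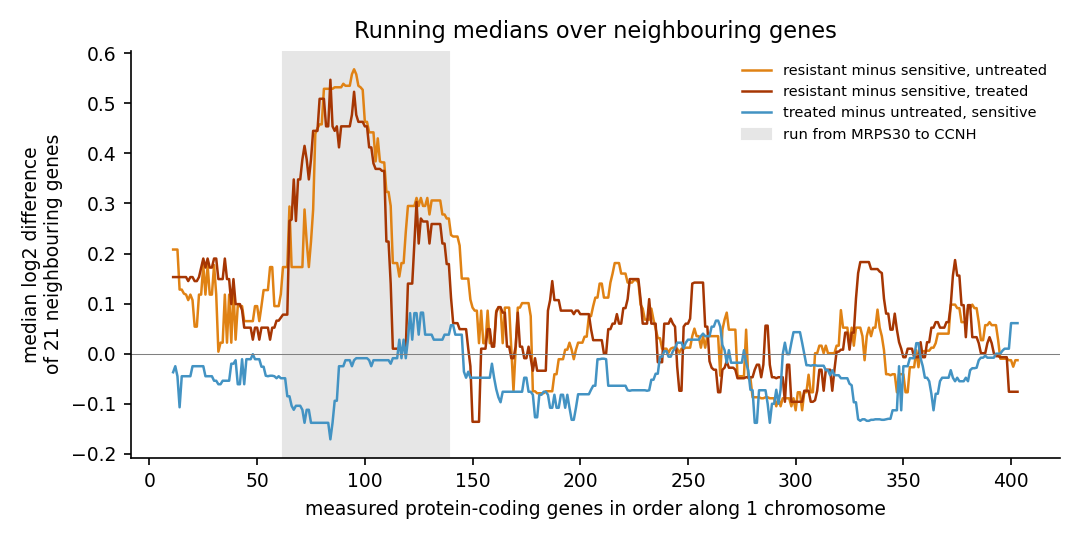
Running medians over 21 neighbouring genes along 1 chromosome of the log2 difference between resistant and sensitive cells without and with antibody and of the response of sensitive cells. The grey band marks the 78 genes from MRPS30 to CCNH, where the difference has a median of 0.38 without and 0.35 with antibody and the response a median of -0.04.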

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

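Of the tests in this part, the splits of the arrays and the list tests with camera and fry were chosen before the data were examined, while the list tests without single arrays, the tests of neighbouring genes and the tests of explanations were chosen only after the result was seen.

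Of the 35 splits of the 8 arrays into 4 and 4, the real one, resistant against sensitive, called 2018 genes and the highest of the others called 0, so that 1 split gave as many. Every other split mixes both populations, which widens the spread within its groups. The split by treatment called 0 as well, although 619 genes changed with trastuzumab in sensitive cells. The 0 counts therefore cannot decide about chance, and chance differences between cultures stay open.

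A test of the difference between responses pointed to 7 gene lists. The response to trastuzumab differed between resistant and sensitive cells for G1/S and DNA replication genes (median 0.53), G2/M and mitosis genes (0.41), cholesterol synthesis genes (0.39) and fatty acid synthesis genes (0.22). With an estimated correlation these 4 calls were lost (adjusted p = 0.14 for each). The response also differed for oestrogen receptor targets (median 0.15, adjusted p = 0.011, and adjusted p = 0.59 with an estimated correlation). For FOXO targets the median was -0.07 (adjusted p = 0.02, and adjusted p = 0.22 with an estimated correlation), and for ribosomal genes -0.10 (adjusted p = 0.026, and adjusted p = 0.59 with an estimated correlation). The median FOXO response given above was not smaller in resistant cells, while the FOXO score rose by 0.30 in sensitive and 0.15 in resistant cells. For FOXO targets the direction thus depends on the measure. The last 3 calls were lost without array 2 of the treated sensitive cells (adjusted p of 0.055, 0.11 and 0.055) and with fry (0.27, 0.12 and 0.23). Without array 1 of the untreated sensitive cells the oestrogen receptor call had an adjusted p of 0.25, and without array 1 of the treated resistant cells the ribosomal call had 0.34.

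For the smaller response of proliferation genes in resistant cells a property of these cells may be 1 explanation among several that stay open. The G1/S scores of the responses differed by 0.54 (SE 0.07), but the list was picked by this difference and the spread between arrays may be technical, so chance differences between cultures stay open. Compressed values on the treated resistant arrays would have enlarged the fall, since the G1/S genes lay a median of 3.90 (SD 0.73) above the array median in untreated resistant cells. Antibody left over in untreated cultures of cells otherwise like the sensitive ones would have lowered their G1/S score, which was higher by 0.23 (SE 0.05). Left-over antibody in cells with a higher level of their own stays open, as do the unstated dose and time of treatment.

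The higher interferon-stimulated genes and the chemokines CCL5 and CXCL10 of resistant cells may be a property of the population, a hypothesis found and tested on the same data. RNA from blood or immune cells would bring its markers along, and these had a median of -0.13 (SD 0.17) over both treatment states. Only 8 of 18 listed markers were measured, so this covers those markers alone. Antibody present at harvest would raise the list with treatment, and in resistant cells its median was -0.06 (its score's 95% interval reached 0.09 to either side). Antibody left over in the untreated resistant cultures would hide such a rise. Their time without antibody is not given, so left-over antibody stays open. Extra copies of the region around CCL5 would raise its neighbours, and the 20 measured ones had a median of 0.06 (SD 0.22). Long exposure to the antibody, an infection of the culture and passage number were not tested and stay open.

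The runs of neighbouring genes that were higher in resistant cells may reflect different copy numbers of these regions in the 2 populations. A chance order of the changed genes gave a window as large in 0 of 1000 shuffles (highest 0.41 against 0.50). Neighbours that shift together in any comparison would move the run genes with treatment too, and their median in treated against untreated sensitive cells was -0.05 (spread of the runs 0.06), although single runs reached -0.12 (TSSK6 to NUDT19, HEATR1 to ZNF496 and KLF10 to DSCC1) and -0.17 (ODF2 to ASS1). Adjacent genes were weakly correlated beyond all shuffles in every comparison, however (r = 0.04, 0.035 and 0.036 in the responses and the interaction, p = 0.001 each, the smallest that 1000 shuffles can give), so a smaller common shift of neighbours stays open. A copy number difference would shift the runs alike in the untreated and the treated comparison, which share no array, and window medians across the genome correlated at 0.81 (0.32 between the 2 responses), but no DNA was measured and regulation of whole regions stays open.

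Probe sets without a gene name in the annotation used, which the report's comparisons do not include, held a signal: 1727 of 37519 differed between resistant and sensitive cells over both treatment states, 1045 higher and 682 lower, with log2 differences from -5.59 to 3.24. By limma 0 of them changed with trastuzumab in either population.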

How the results depend on the processing

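Leaving out arrays for list tests and correlations was chosen after seeing the data; the other alternatives were not. Of 14884 genes, the untreated comparison of resistant with sensitive cells called 1742 instead of 1100 with the filter on dim genes, 1973 with a variance trend and robust moderation, 664 with only the 4 arrays compared, 131 with a change of at least 1 on the log2 scale, and 265 to 958 with single arrays left out. The treated comparison called 1105 instead of 1738 with only the 4 arrays compared, 184 with a change of at least 1, and 723 to 1638 with single arrays left out. The response of sensitive cells called 1028 instead of 619 with the filter, 1271 with the trend, 220 with only 4 arrays, 146 over all probe sets, 48 with a change of at least 1, and 101 to 477 with single arrays left out. The response of resistant cells called 4 instead of 0 with the filter and 34 with the trend, the averaged comparison 140 instead of 3001 with a change of at least 1 and 1864 to 2644 with single arrays left out, and the interaction 37 instead of 0 with the trend. Fewer arrays and the size limit lower counts by construction; for the filter, the trend and all probe sets the cause was not tested. The other count settings, the replicate block below apart, stayed within 1.5 times of the counts reported. The correlation of the untreated with the treated comparison was 0.78 with the filter and 0.63 to 0.677 with single arrays left out, and that of the 2 responses 0.47 and 0.239 to 0.35.

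Signs reversed for values that passed in no setting: ERBB3 in the untreated comparison was 0.02 with centred arrays and -0.038 to 0.004 with single arrays left out, and EGFR in the response of resistant cells was 0.055 with quantile normalization and -0.079 to 0.079 with single arrays left out; the cause was not tested. Of 479 named gene values, 459 kept their side of the threshold with centred arrays, 461 with quantile normalization, 341 over all probe sets and 384 to 430 with single arrays left out. Of 54 list calls, 53 were kept with centred arrays, 49 with the filter, 48 with fry, 5 with an estimated correlation and 42 to 52 with single arrays left out, and 0 reversed. A lone array left in a group is assumed to vary like the other groups. With the replicate number as a block, 787, 1380, 408, 0, 2633 and 0 genes were called in the 6 comparisons (untreated, treated, sensitive response, resistant response, averaged, interaction) and 53 list calls were kept. Differences between replicates correlated at -0.18 to 0.21 between groups, which shows no strong effect of the number common to the groups. These values cannot decide whether arrays with the same number shared a culture or a day. Background per array is not given in the sources used here, so no limit of detection was set for dim genes.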

Other observations

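Further lists, fixed before the data were examined, moved in both directions between untreated resistant and sensitive cells without being called. Of 24 S100 and epidermal defence genes, 4 were lower and 2 higher (median -0.14): the protease inhibitor SLPI (-1.56) and the cornified envelope protein IVL (-0.99) were among the lower ones. IVL lay below the array medians in untreated resistant cells (4.79 and 4.85), so its difference is not exact. FOXO targets had 3 higher and 2 lower of 19, 6 and 3 when adjusted over the list alone, with BCL6 (-0.93) and CCNG2 (-0.71) lower. Of 25 other receptor tyrosine kinases and ligands, 4 were higher and none lower, 7 and 3 when adjusted over the list alone (median -0.01). Single genes of further lists were DKK1, a Wnt inhibitor (-1.78), SOX9 (-0.88) and the glutathione transferase GSTM3 (0.82).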
